A study of Danio rerio with 12 samples.

How the data were processed

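The study profiled dissociated zebrafish brain by droplet single-cell RNA sequencing (10x Genomics Chromium, 3' chemistry, version 3) in 12 libraries, 3 in each of 4 groups. The transgenic line drives human alpha-synuclein (aSyn), joined to a green fluorescent protein by a self-cleaving peptide, from a UAS promoter under a HuC:Gal4 driver that is active in neurons, per the labels. At 5 days post fertilisation (dpf) the groups were aSyn larvae (libraries A, B and C) and control larvae without the transgene (A, B and C). At 4 weeks post fertilisation (wpf) both groups carried aSyn and had been fed daily from 5 dpf, on control food (libraries 1, 5 and 7) or on food with sonicated human aSyn preformed fibrils (PFF; libraries 2, 6 and 8). The series design calls the libraries biological replicates, and the number of fish in each library is not given in the sources used here. The extraction protocol gives an age of 5 dpf for all 12 libraries, including those that the series design places at 4 wpf. The sample titles call the control-food libraries Nonfed and the PFF libraries Fed, read here as without and with PFF. The titles alone do not say that the control group was fed. The series design also names larvae without the transgene that were fed PFF; that group was not used here.

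The deposited matrices hold raw UMI counts per gene and cell barcode, made with Cell Ranger 7.2.0 for the 5 dpf libraries and Cell Ranger 7.0.1 for the 4 wpf libraries, per the file headers. The genome build was GRCz11, per the submitters' processing notes, which also name R 4.1.0 and Seurat 4.0.3. Every value used here was computed again from the deposited counts, and no deposited cell annotation or normalised value was used. The tables of the 5 dpf libraries share 25432 genes and those of the 4 wpf libraries 25433, since the tables of the 5 dpf controls have no GFP feature. GFP was the readout of the transgene and could not be compared with the 5 dpf controls. Of the 7667 genes that the 4 wpf tables list by ID alone, 5860 took a symbol from a table of gene IDs; gene names were also looked up in a RefSeq gene table made on another assembly (GRCz12tu), which served for names only.

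Cells were kept with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs. Doublets were scored with Scrublet as implemented in scanpy 1.11.5. Its automatic threshold marked under 0.5% of the cells in 11 of the 12 libraries, so the highest scores were marked instead, at 0.8% of the cells per 1000 cells and at most 10%, and removed. Clusters were built per age, before the doublets were removed, with the Leiden algorithm of igraph 0.11.9 at resolution 1. They used 2000 variable genes, 30 principal components and 20 neighbours. A cluster was called X-like from marker genes fixed before the data were examined. It needed at least 20 cells, at least 3 detected markers of the class, each with a log2 fold of at least 0.5 and found in at least 20% of its cells, at least 33.3% of the class's markers, a median doublet score of at most 0.2, and leading genes that did not go against the name; other clusters stayed unnamed. Shares of a class were taken over all kept cells of a library and compared with a 2-sided exact permutation test over the 20 assignments of 3 libraries against 3, whose smallest p is 0.1. At 5 dpf the shares were also compared within letters with an exact sign-flip test, chosen after the data were seen.

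For expression, the UMIs of all kept cells, and of the neuron-like, microglia-like and radial glia-like cells, were summed per library, so that a library and not a cell was the replicate. The sums were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, its default filter on low counts) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. These p-values measure the spread between libraries. CPM are counts per 1e6 UMIs of the summed class. For single genes from the edgeR test the library sizes were taken over the genes tested alone and scaled by the TMM factors. Sums of marker genes, mfap4 sums, and GFP and elavl3 given by cell class and library were not scaled. Marker sums of every class were compared in each of these sums with the exact permutation test, and only some are given. A random order of the libraries gives the smallest p in 10% of such comparisons. Before the data were examined 32 gene lists were fixed, of which at most 31 had the 5 tested members needed for a test. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), with camera using an estimated correlation and with fry beside it. Effects were compared between cell classes with an interaction term in edgeR, with library as a block. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and pyarrow 21.0.0 handled the matrices, and matplotlib 3.10.9 drew the plots.

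Genes were named by a rule fixed before the data were examined. GFP, elavl3, sncb, sncga and sncgb were named in every comparison where they were tested. To these came the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, groups that do not overlap and a mean of at least 10 CPM. Where no gene passed in a direction, the 5 genes with the smallest p and a mean of at least 10 CPM were given as values that did not pass. Clone and accession names were skipped, and a few genes that the rule takes in are not reported. The members of a list with the smallest p were named too; the limits of 3 members and of the 6 lists with the smallest p were set after the values were seen. A gene with 3 or fewer UMIs in a group is given as a ratio of UMI rates with its exact 95% counting interval, or, at 0 UMIs, as a bound against 3 UMIs over the group. Such intervals cover counting error only.

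Both steps were tested on simulated counts drawn with the means and library sizes of each comparison, with 200 genes changed by known folds. In the 4 wpf neuron-like sums, over 17500 genes, edgeR recovered 31.8% of the genes changed by a log2 fold of 1, 95.5% of those changed by 2 and 95.4% of those changed by 3, with 6.4% false calls. In the 5 dpf microglia-like sums, over 2898 genes, it recovered 12.7%, 88.9% and 96.8%, with 6.1% false calls. In the 4 wpf microglia-like sums, over 7588 genes, it recovered 6.1%, 73% and 98.5%, with 6.5% false calls. With 200 genes changed at once, the adjusted threshold is easier to pass than where few genes change. No letter pairing or other structure between libraries was simulated. The recovered shares may thus be too high for the real sums. DESeq2 gave 26.3% false calls in the simulated 5 dpf sums of all cells and 24.7% in those at 4 wpf, where edgeR gave 6.1% and 11.3%. In the microglia-like sums DESeq2 was close to edgeR, at 5.5% at 5 dpf and 8.6% at 4 wpf. In the 5 dpf neuron-like and radial glia-like sums edgeR gave 10.6% and 10.7%, and DESeq2 13.2% and 10.9%. A shift of 0.5 on the log2 scale in 43 simulated lysosome genes of the 5 dpf microglia-like sums gave an adjusted p of 1.36e-07 with camera, 0.237 with an estimated correlation and 0.112 with fry, so the last 2 tests missed a shift of that size there. In the simulated 4 wpf microglia-like sums they gave 0.049 and 0.0368. In the simulated neuron-like sums they gave 0.00162 and 0.000342 at 5 dpf and 0.0045 and 0.00133 at 4 wpf. The shift was thus found in those simulated counts. Genes were drawn independently of each other there. This therefore does not show that either test would find such a shift where genes of a list vary together.

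The depth after filtering was 58.1 to 79.1 M UMIs (M, 1e6) per library at 5 dpf and 29.2 to 96.3 M at 4 wpf. Replicates differed by more than sampling noise: the chi-square per gene between libraries of one group ran from 77.5 to 331.7, so the spread between libraries, not counting error, set the precision. The microglia-like sums were the shallowest, with 0.24 to 0.55 M UMIs at 5 dpf and 0.24 to 1.47 M at 4 wpf.

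The letters A, B and C occur in both 5 dpf groups, while the 4 wpf groups share no library numbers. Correlations of the deviations from the group means between libraries of the same letter were 0.266, 0.181 and 0.259 in all cells. They were 0.444, 0.181 and 0.211 in neuron-like cells and 0.312, 0.122 and 0.251 in radial glia-like cells. In these 3 sums the letters were taken to pair the libraries; where the pairing comes from is not stated in the sources used here. In microglia-like cells they were 0.041, -0.049 and 0.237, and the letters were not taken to pair them. The main design has no block for the letter, and the fit with it is an alternative.

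Alternatives tried were DESeq2 1.42.0, edgeR with RLE factors, other filters on low counts, at least 1000 UMIs per cell, at most 5% mitochondrial UMIs and doublets kept. Others were clusters at resolution 0.5, expression centred per library before clustering, counts thinned to the smallest total, a filter for genes as high in the class as in all cells against free RNA, the letter as a block, and each library left out in turn. Class comparisons beyond the 3 classes named above were limited to their shares. The 4 wpf control-food libraries were also set beside the 5 dpf aSyn libraries; age, food, preparation and software version all differ between them.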

Results

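Brain cells from 12 zebrafish libraries were profiled to ask how neurons and microglia respond to neuronal human aSyn in 5 dpf larvae and to PFF feeding in 4 wpf fish that carry aSyn, a design that the study places in the context of Parkinson's disease. The 5 dpf aSyn libraries held 66.0 (A), 84.4 (B) and 62.4 (C) M UMIs (M, 1e6) over 7089, 4211 and 4091 barcodes. The 5 dpf control libraries held 82.9 (A), 63.8 (B) and 68.5 (C) M UMIs over 7171, 5190 and 6829 barcodes. At 4 wpf the control-food libraries held 101.5 (1), 103.0 (5) and 105.4 (7) M UMIs over 23676, 10412 and 24498 barcodes, and the PFF libraries 65.1 (2), 90.2 (6) and 30.8 (8) M UMIs over 13137, 12715 and 4605 barcodes. After filtering, the kept cells ran from 3835 (aSyn C) to 20817 (control food 7) per library, and their median depth from 1829 UMIs (control food 7) to 6445.5 (control food 5).

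The transgene's GFP was read in neuron-like cells at a higher rate than in radial glia-like cells. In the 5 dpf aSyn libraries the neuron-like cells held 19.84, 24.46 and 22.92 CPM of GFP, and the radial glia-like cells 0.76, 0 and 1.29 CPM. Oligodendrocyte precursors held 20.51, 25.05 and 8.27 CPM and oligodendrocytes 9.69, 18.71 and 14.52 CPM, from 2 to 7 UMIs each. These 2 classes also held 746.6 to 1447.7 CPM of neuronal elavl3, against 99.6 to 136.0 CPM in the radial glia-like cells, so their GFP may be RNA from neurons. At 4 wpf the neuron-like cells held 33.2 ± 12.7 CPM (SD, n = 3) with PFF food and 29.7 ± 7.74 CPM with control food, a log2 fold change of 0.15 ± 0.28 (SE; edgeR, adjusted p = 1). Transcripts of elavl3, the gene behind the HuC promoter, stood at 2841 ± 225 CPM with PFF food and 2714 ± 295 CPM with control food in the same cells.

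In 5 dpf larvae no share of the main cell classes separated the groups. Neuron-like cells made up 43.8 ± 7.56% of the kept cells with aSyn and 52.4 ± 6.14% in controls (SD, n = 3; exact permutation p = 0.2). Paired by letter, the share was lower with aSyn in each pair, at 52.4 against 54.2% (A), 38.2 against 57.5% (B) and 40.8 against 45.6% (C). The mean difference was -8.6458 percentage points (SD 9.3695; exact sign-flip p = 0.25, 2-sided, the smallest that 3 pairs allow). Radial glia-like cells, the neural stem and astroglial cells of the fish brain, made up 10.2 ± 1.53% and 8.66 ± 1.41% (exact permutation p = 0.4, n = 3). Microglia-like cells made up 0.669 ± 0.155% and 0.595 ± 0.157% (exact permutation p = 0.7, n = 3). The smallest p that 3 libraries against 3 allow is 0.1. Unnamed clusters held 24.4 ± 4.91% of the aSyn cells and 19.1 ± 3.47% of the control cells. One of these had 12 markers of fibroblasts or meninges. It held 721, 429 and 671 cells of aSyn A, B and C and 394, 463 and 639 of the controls. The largest epithelium-like cluster held 161, 197 and 132 cells with aSyn and 250, 199 and 209 in controls. Such cells enter the denominator, so the neuron-like share was not separated from the amount of other tissue in each library.

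**Figure D1:**
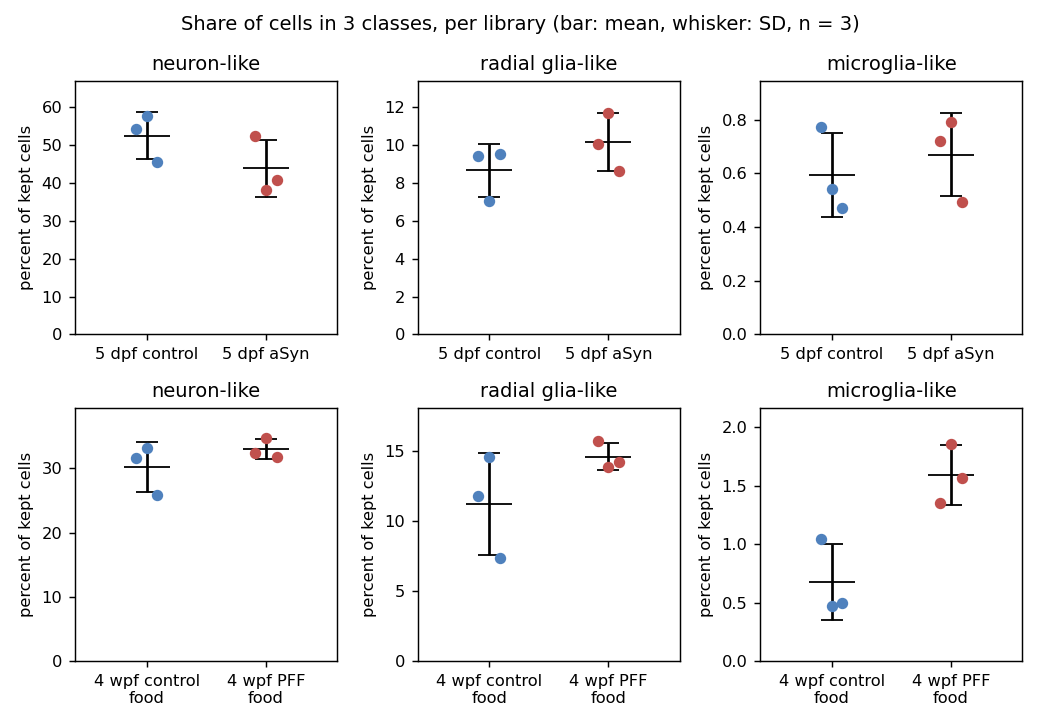
Percent of the kept cells of each library in the neuron-like, microglia-like and radial glia-like classes at 5 dpf and 4 wpf; each point is a library, the bar is the mean and the whisker the SD (n = 3). The microglia-like share at 4 wpf lies between 1.35% and 1.86% with PFF food and between 0.478% and 1.05% with control food.

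In the microglia-like cells at 5 dpf no gene passed the threshold. Among the values that did not pass, the immune genes cxcl8a, il1b and csf3b were lower with aSyn, and the CC chemokine genes ccl38a.3 and ccl36.1 were higher. The neutrophil-attracting chemokine cxcl8a stood at 102 ± 37.0 CPM with aSyn and 755 ± 302 CPM in controls, a log2 fold change of -2.855 ± 0.38 (SE, n = 3; edgeR, adjusted p = 0.0535). The pro-inflammatory cytokine il1b stood at 187 ± 78.4 CPM against 946 ± 509 CPM, and the granulocyte growth factor csf3b at 5.35 ± 7.42 CPM against 284 ± 284 CPM. In the other direction, ccl38a.3 stood at 328 ± 82.7 CPM with aSyn and 8.52 ± 14.8 CPM in controls. Each of these genes separated the 3 aSyn libraries from the 3 control libraries. A random order of 6 values does so with a chance of 10% for a gene chosen beforehand. These genes were picked for a small p in the same data, so their separation adds no support.

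None of the 3135 genes tested in these cells passed in edgeR, while 191 had an unadjusted p under 0.05 and DESeq2 called 18, of which 3 were higher and 15 lower. The genes nearest the threshold in edgeR were cxcl8a, ccl36.1 and olfm4l2, each with an adjusted p of 0.0535. The CC chemokine ccl36.1 had 87 UMIs in the aSyn libraries and 2 in the controls, a 46.4-fold higher rate (95% counting interval 12.5 to 389). The olfactomedin genes olfm4l2 and olmf4l1, related to a mammalian gene of neutrophil granules, had log2 fold changes of -2.195 ± 0.31 and -2.44 ± 0.45. For mfap4.2, of a family expressed in zebrafish macrophages, the value was -1.75 ± 0.28, for csf3b -5.83 ± 1.09 and for il1b -2.33 ± 0.49. Higher values that did not pass were those of ccl38a.3 (4.86 ± 0.77), the HMG-box factor tox2 (2.28 ± 0.47), the glycosyltransferase mgat4b (2.11 ± 0.53) and the ubiquitin ligase TTC3 (1.44 ± 0.36). Their adjusted p in edgeR ran from 0.0876 to 0.43. The pan-neuronal elavl3 had a value of -0.84 ± 0.60. With the letter as a block, edgeR called 5 genes, ccl36.1 higher and cxcl11.3, cxcl8a, olfm4l2 and olmf4l1 lower. Without control A, 1 gene passed (ccl38a.3, higher).

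**Figure D2:**
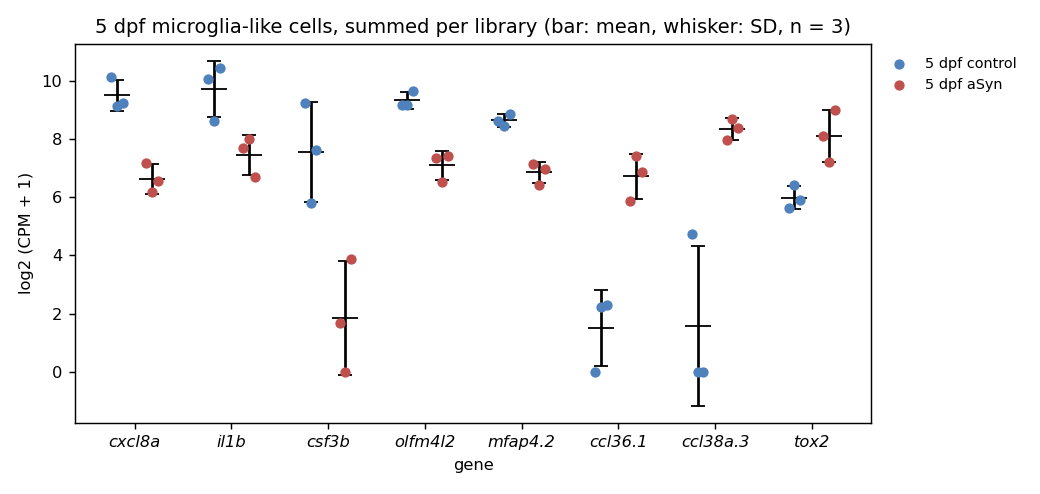
Expression in the microglia-like cells of 5 dpf larvae as log2(CPM + 1), by library, with controls in blue and aSyn in red; the bar is the mean and the whisker the SD (n = 3). The aSyn libraries lie below the controls for cxcl8a, il1b, csf3b, olfm4l2 and mfap4.2 and above them for ccl36.1, ccl38a.3 and tox2.

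Of the 26 gene lists tested in the microglia-like cells, camera called 6. The microglial activation list was lower (adjusted p = 4.67e-06, and 0.53 with an estimated correlation), with 20 of 28 members below 0 and a median log2 fold change of -0.458. Adjusted over the list alone, 2 members fell, cxcl8a and il1b; over all genes tested none passed. The lysosome list was lower (adjusted p = 0.0019, and 0.836 with an estimated correlation), with 32 of 44 members below 0 and a median of -0.303. Its members with the smallest p were the proton pump subunits atp6v0ca (-0.81 ± 0.23) and atp6v1ba (-0.795 ± 0.24) and grna (-0.92 ± 0.30), which encodes a progranulin. Nuclear genes of oxidative phosphorylation were lower (adjusted p = 0.00299, and 0.836 with an estimated correlation), with 68 of 81 below 0. Of these, atp5mc1 stood at -0.655 ± 0.26 and atp5f1c at -0.65 ± 0.35, while sdhc, of complex II, stood at 0.71 ± 0.32.

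Camera called 3 lists higher in the same cells. Cell cycle genes were higher (adjusted p = 0.000119, and 0.836 with an estimated correlation), with 21 of 24 members above 0 and a median of 0.511. The replication helicase genes mcm4 and mcm6 stood at 1.22 ± 0.34 and 1.1 ± 0.34, and stmn1a, a regulator of microtubules, at 1.5 ± 0.56. The groups overlapped for stmn1a, since aSyn B (56.66 CPM) lay below all 3 controls. Ribosomal protein genes were higher (adjusted p = 4.67e-06, and 0.836 with an estimated correlation), with 82 of 84 above 0 and a median of 0.239. The genes rplp2, rpl37 and rps29 stood at 0.32 ± 0.20, 0.36 ± 0.23 and 0.31 ± 0.20. The immediate-early and dissociation list was higher (adjusted p = 0.0454, and 0.836 with an estimated correlation), with 34 of 49 above 0. The glucocorticoid-induced tsc22d3 stood at 0.70 ± 0.24 and the phosphatase gene dusp1 at 0.85 ± 0.30, while the cytokine inhibitor socs3b stood at -1.13 ± 0.40. No member of these 5 lists passed, over all genes or adjusted over the list alone. The fry test called 0 lists, and without control B camera called 3 lists, where all libraries gave 6. With the letter as a block, which was not taken to pair these sums, camera called 7 lists, and 0 with the block and an estimated correlation. The summed markers of neutrophils fixed beforehand stood at 737 ± 252 CPM in these sums with aSyn and 1394 ± 320 CPM in controls (exact permutation p = 0.1, n = 3). Those of mural cells stood at 160 ± 48.0 and 101 ± 38.62 CPM (exact permutation p = 0.1, n = 3).

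In the 5 dpf neuron-like cells, where the promoter of the transgene is active, no gene passed without a block for the letter. Among the transcripts of the fish's own synucleins, sncb had a log2 fold change of -0.07 ± 0.12, sncga of 0.07 ± 0.60 and sncgb of -0.06 ± 0.13 (SE, n = 3; edgeR, adjusted p = 1). The sncga value rests on aSyn B, at 24.38 CPM against 3.856 and 5.741 CPM in A and C and 8.483, 15.21 and 7.482 CPM in the controls. It was -1.14 without aSyn B and -0.173 with the letter as a block. For elavl3 the value was 0.05 ± 0.13. The largest differences among the named genes were in genes with a wide spread between libraries. Of these, gnrh2, of gonadotropin-releasing hormone 2, stood at 76.1 ± 127 CPM with aSyn and 1.14 ± 1.06 CPM in controls. The parathyroid hormone family gene pth2 stood at 1.21 ± 1.07 CPM against 52.8 ± 69.1 CPM.

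Of 17278 genes tested in the neuron-like cells, 0 passed in edgeR and 0 in DESeq2, and 185 had an unadjusted p under 0.05. Higher values that did not pass were those of the nuclear receptor nr5a2 (0.63 ± 0.17), the retinol-binding rbp4l (4.62 ± 1.67), the gap junction gene gjd2b (0.595 ± 0.23) and gnrh2 (5.96 ± 1.76). The groups overlapped for gjd2b, rbp4l and gnrh2, and for the last 2 the aSyn mean rests on library B, at 154.2 and 223.1 CPM. Lower values that did not pass were those of pth2 (-5.56 ± 1.25), the axon guidance cue ntn1a (-0.60 ± 0.16), the tRNA methyltransferase trdmt1 (-0.52 ± 0.14), the Hsp70-binding hspbp1 (-0.49 ± 0.14) and elongin C (eloca, -0.435 ± 0.13). With the letter as a block, 1 gene passed, pth2, lower with aSyn.

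Camera called 4 of 31 lists in these cells, none with an estimated correlation (adjusted p = 0.872 for each) or with fry. The microglial activation list was lower (adjusted p = 2.63e-06), with 29 of 33 members below 0 and a median of -0.183. The members with the smallest p were csf1b (-1.475 ± 0.50), fabp4a (-0.80 ± 0.27) and the matrix protease mmp9 (-1.075 ± 0.45), all under 6 CPM on average. Markers of other cells were read in these sums too. Endothelial markers stood at 46.65 ± 1.157 with aSyn and 53.2 ± 0.592 CPM in controls (exact permutation p = 0.1, n = 3), with no overlap. Those of neutrophils, at 10.62 ± 0.9323 and 14.33 ± 5.145 CPM (exact permutation p = 0.3, n = 3), and of microglia, at 164.3 ± 27.98 and 193.4 ± 58.48 CPM (exact permutation p = 0.4, n = 3), overlapped. Among the cell clusters, fabp4a was a leading gene of endothelial cells and mmp9 of neutrophils. The immediate-early and dissociation list was lower (adjusted p = 3.36e-05), with 60 of 71 below 0 and a median of -0.117. The activity-dependent npas4a stood at -0.26 ± 0.11, fosl2 at -0.23 ± 0.11 and sik1 at -0.29 ± 0.15. Ribosomal protein genes were higher (adjusted p = 2.63e-06), with 81 of 91 above 0 and a median of 0.083. Among them rpl37 stood at 0.17 ± 0.16, the ribosomal protein gene copy rps11l at -0.41 ± 0.33, and rps6kc1, a kinase gene that the name pattern of the list also takes in, at 0.16 ± 0.12. Genes of neurogenesis were higher (adjusted p = 0.00136), with 51 of 64 above 0 and a median of 0.061; notch1b stood at 0.61 ± 0.26, its ligand gene dlb at 0.395 ± 0.18 and sox4a at 0.19 ± 0.11. None of the members passed, over all genes or adjusted over the list alone. With the letter as a block camera called 10 lists, and it added neuropeptides (lower, adjusted p = 2.74e-07), glucocorticoid response (lower, 0.0174), proteasome (higher, 0.0174), chaperones (lower, 0.0334), synaptic vesicle genes (lower, 0.0408) and glycolysis (lower, 0.0464). With the block and an estimated correlation it called 0, with an adjusted p of 0.796 for each of the 10. Camera called 7 lists without aSyn B and 8 without control B.

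Among the 5 dpf radial glia-like cells the LIM homeobox gene lhx5 stood at 39.8 ± 3.91 CPM with aSyn and 14.02 ± 1.70 CPM in controls, a log2 fold change of 1.5 ± 0.19 (SE, n = 3; edgeR, adjusted p = 0.118). Of 13798 genes tested, 0 passed in edgeR, 277 had an unadjusted p under 0.05, and DESeq2 called 2, lhx5 and arf4b, both higher. Other higher values that did not pass were those of PEX5L (1.55 ± 0.35), the Wnt antagonist sfrp5 (1.02 ± 0.25) and complement factor D (cfd, 2.46 ± 0.62). The cfd mean rests on aSyn B, at 161 CPM against 26.73 and 28.77 CPM in A and C and 13.04, 13 and 13.28 CPM in the controls. Lower values that did not pass were those of the claudin-related cldc1 (-2.01 ± 0.47), the glypican gpc1a (-1.085 ± 0.255), the transcription factor helt (-1.12 ± 0.27), the monocarboxylate transporter slc16a6b (-1.08 ± 0.26) and cmbl (-0.78 ± 0.21). The values of elavl3, sncb, sncga and sncgb were 0.19 ± 0.17, -0.14 ± 0.295, 0.11 ± 0.30 and -0.02 ± 0.34. Without aSyn B, 5 genes passed, all higher (clu, slc13a3, gipr, bmp1b and 1 with a clone name).

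Summed over all kept cells, 1 of 21723 genes passed at 5 dpf. It was the odorant receptor gene or62b5, with 3 UMIs in the aSyn libraries and 268 in the controls, an 88.5-fold lower rate (95% counting interval 30 to 432), and it no longer passed with the letter as a block (0 genes). An unadjusted p under 0.05 was reached by 366 genes, and DESeq2 called 22, of which 18 were higher and 4 lower. Higher values that did not pass in edgeR were those of the galectin lgals2b (7.28 ± 1.097), the transcobalamin tcnba (8.19 ± 1.67), asip2b (0.73 ± 0.19), the peroxiredoxin prdx1 (0.65 ± 0.185) and tshba, the beta subunit of thyrotropin (6.89 ± 2.00), for which aSyn C lay below the controls. Lower values that did not pass were those of the receptors gpr3 (-0.62 ± 0.19) and CHRM3 (-0.55 ± 0.18), ZNF532 (-0.505 ± 0.17), mmp9 (-1.96 ± 0.655) and the synaptotagmin syt13 (-0.535 ± 0.18). The groups overlapped for mmp9, with control B at 9.966 CPM, below aSyn B and C at 12.1 and 16.14 CPM, and controls A and C at 63.48 and 74.53 CPM. Digestive organ markers summed to 93.8 ± 128 CPM with aSyn and 13.4 ± 1.45 CPM in controls (exact permutation p = 0.1, n = 3), and the aSyn mean rests on library B. Markers of pigment cells, at 128.2 ± 9.646 and 99.25 ± 14.12 CPM, and of mural cells, at 240.2 ± 14.66 and 207.9 ± 23.89 CPM, were higher with aSyn too (exact permutation p = 0.1 each, n = 3). Many marker classes were compared in these sums, and 10% of them would reach this p in a random order of the libraries. Neuronal elavl3, sncb, sncga and sncgb stood at -0.30 ± 0.26, -0.48 ± 0.24, -0.25 ± 0.22 and -0.515 ± 0.20. The share of neuron-like cells was lower with aSyn in each letter pair, and these sums do not separate it from a change within neurons. Without aSyn A, 5 genes passed, and without any one of the other 5 libraries 0 did.

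At 4 wpf, the comparison of PFF with control food asks what ingested fibrils do in brains whose neurons make aSyn. Microglia-like cells made up 1.59 ± 0.253% of the kept cells with PFF food and 0.676 ± 0.324% with control food (SD, n = 3; exact permutation p = 0.1, the smallest the design allows), and every PFF library lay above every control-food library. With at least 1000 UMIs per cell the difference was 0.673 percentage points in place of 0.917, and the groups overlapped (exact permutation p = 0.2). The same order held for mural cells, which line blood vessels, at 0.774 ± 0.166% and 0.450 ± 0.156% (exact permutation p = 0.1, n = 3). Of the 2 microglia-like clusters, the larger, led by ccl34b.1, lgals3bp.1, lgals9l1, havcr1 and il1b, held 1.31 ± 0.369% and 0.405 ± 0.161% of the cells (exact permutation p = 0.1, n = 3). The smaller, led by ccl35.1, mhc2daa and cd74a, held 0.282 ± 0.181% and 0.270 ± 0.166% (exact permutation p = 0.9, n = 3).

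Other shares at 4 wpf overlapped between the groups. Neuron-like cells made up 32.9 ± 1.56% with PFF food and 30.2 ± 3.85% with control food (exact permutation p = 0.4, n = 3). Radial glia-like cells made up 14.6 ± 0.986% and 11.2 ± 3.64% (exact permutation p = 0.3, n = 3). Cycling progenitors made up 7.12 ± 1.16% and 8.39 ± 4.79% (exact permutation p = 1, n = 3), and oligodendrocytes 2.82 ± 0.375% and 2.59 ± 1.28% (exact permutation p = 0.9, n = 3). Unnamed clusters held 25.7 ± 5.1% and 34.3 ± 15% of the cells. One of them, with a median of 613 UMIs per cell, held 26.34%, 0.6% and 38.17% of control food 1, 5 and 7 and 9.27%, 1.82% and 2.0% of PFF 2, 6 and 8, so the denominators of these shares differ in depth. The neuron-like difference turned to -2.98 percentage points with at least 1000 UMIs per cell and to -4.89 without that cluster. Another cluster, with a median of 3150 UMIs and 4 GABAergic neuron markers, was left unnamed by the rule on leading genes. It held 678, 770 and 311 cells of PFF 2, 6 and 8 and 509, 571 and 910 of control food 1, 5 and 7. So was a cluster of 3936 cells with a median of 12912.5 UMIs and 12 cycling progenitor markers. Neither is counted in the neuron-like or cycling progenitor shares above.

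In the microglia-like cells 4 genes fell with PFF food, 3 of them members of the mfap4 family of macrophage-expressed genes that encode secreted fibrinogen-domain proteins. Over the PFF libraries mfap4.11 had 1 UMI, against 256 with control food, a 222-fold lower rate (95% counting interval 39.5 to 8810; edgeR, adjusted p = 0.0032). For mfap4.8 there were 1 and 323 UMIs, a 280-fold lower rate (49.9 to 11100; adjusted p = 0.0303), and for mfap4.7 there were 0 and 81 UMIs, at least 23.4-fold lower (adjusted p = 0.0319). The fourth gene, ENSDARG00000115195, which has no symbol and was named after its value was seen, had 0 and 178 UMIs, at least 51.5-fold lower (adjusted p = 0.0084). Each was lower in all 3 PFF libraries than in all 3 control-food libraries.

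The counts of mfap4.7, mfap4.8 and mfap4.11 together were 288, 48 and 324 UMIs in control food 1, 5 and 7 and 2, 0 and 0 UMIs in PFF 2, 6 and 8. The other mfap4 genes summed to 293, 212 and 159 CPM in the control-food libraries and to 618, 84.8 and 110 CPM in the PFF libraries. The 5 dpf libraries, which had no PFF, also varied for the 3 genes, with 2, 228 and 36 UMIs in aSyn A, B and C and 82, 0 and 3 UMIs in control A, B and C. Reads from near-identical copies of the family can be split between its members by the counting, so the values of single members are uncertain.

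**Figure D3:**
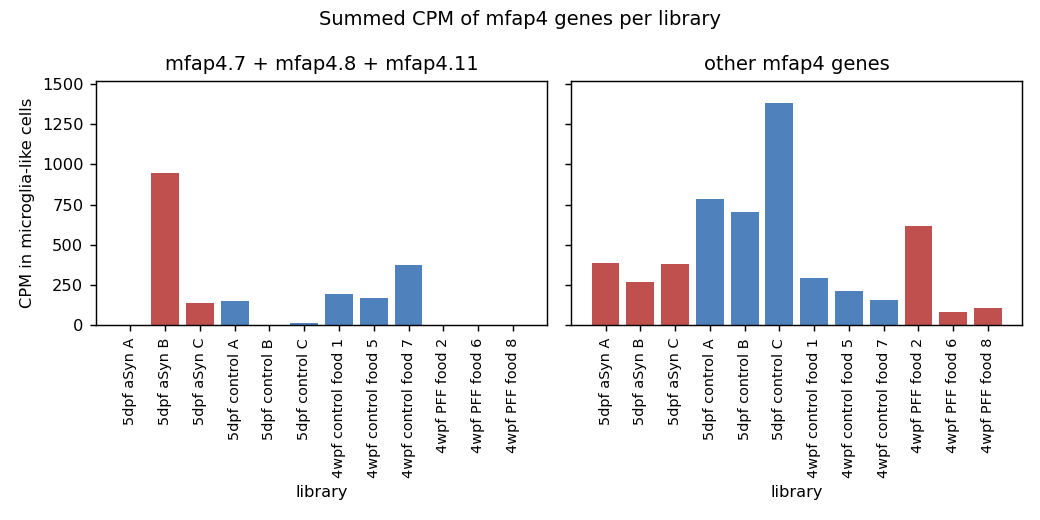
Summed CPM of mfap4.7, mfap4.8 and mfap4.11 and of the other mfap4 genes in the microglia-like cells of each of the 12 libraries, with aSyn (5 dpf) and PFF (4 wpf) libraries in red and their controls in blue. The 3 genes stood at 195, 170 and 374 CPM with control food and at 1.59, 0 and 0 CPM with PFF food, and at 944 CPM in aSyn B and 0 CPM in control B at 5 dpf.

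Of 8036 genes tested in these cells, 200 had an unadjusted p under 0.05, and DESeq2 called 7, all lower, among them the same 4. Without PFF 2, 0 genes passed, without control food 5, 13 did, all lower, and without control food 1, PFF 6 or PFF 8, 2 did. With expression centred per library before clustering, 0 passed. Higher values that did not pass in edgeR were those of the glial bicarbonate cotransporter slc4a4a (1.73 ± 0.36), the apolipoprotein apoeb (0.86 ± 0.21; 5167 ± 1480 against 2856 ± 397 CPM), ralgds (1.44 ± 0.36), the glial adhesion gene hepacama (2.29 ± 0.60) and the cadherin cdh6 (1.91 ± 0.51). Their adjusted p in edgeR ran from 0.784 to 0.999. The values of elavl3, sncb and sncgb were 0.305 ± 0.38, 1.16 ± 0.57 and 0.45 ± 0.78. They rest on PFF 6, at 377.6, 104.6 and 47.2 CPM, against 251.5, 19.99 and 3.331 CPM in PFF 2 and 112, 37.33 and 9.333 CPM in PFF 8. Without PFF 6 they were -0.12, 0.042 and -1.688.

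Camera called 5 of 29 lists in the 4 wpf microglia-like cells. All 10 ways to split the 6 libraries gave at least 5 calls, with 13 the highest. Radial glia and gliosis genes were higher (adjusted p = 1.97e-19, and 0.295 with an estimated correlation), with 32 of 34 above 0 and a median of 0.985. Adjusted over the list alone 1 rose, slc4a4a, while atp1a1b, a sodium pump subunit of glia, stood at 2.02 ± 0.58. Myelin genes were higher (adjusted p = 5.13e-07, and 0.297 with an estimated correlation), with 10 of 11 above 0. Adjusted over the list alone 2 rose, the claudin gene cldnk (2.44 ± 0.67) and gpm6bb (1.17 ± 0.32), while myelin basic protein (mbpa) stood at 0.98 ± 0.37. The markers of radial glia summed to 4064 ± 1657 CPM in these cells with PFF food and 1874 ± 503 CPM with control food (exact permutation p = 0.1, n = 3). Those of fibroblasts summed to 232 ± 37.0 and 120 ± 41.1 CPM (exact permutation p = 0.1, n = 3), and those of oligodendrocytes to 1265 ± 856 and 429 ± 263 CPM (exact permutation p = 0.2, n = 3). The median depth of the microglia-like cells was 7487.5, 2000 and 1761 UMIs in PFF 2, 6 and 8 and 6330.5, 6558 and 6327 UMIs in control food 1, 5 and 7.

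Genes of the unfolded protein response were lower in the microglia-like cells (adjusted p = 0.000438, and 0.916 with an estimated correlation), with 32 of 39 below 0. The chaperone gene hyou1 of the endoplasmic reticulum stood at -1.26 ± 0.42, sel1l, which serves in protein disposal there, at -1.04 ± 0.47 and sec61b of the translocon at -0.53 ± 0.25. Cytosolic chaperones were lower (adjusted p = 0.0244, and 0.916 with an estimated correlation), with 28 of 39 below 0. The heat shock factor hsf1 stood at -1.40 ± 0.475, dnajb1b at -1.83 ± 0.65 and hsp70l at -2.05 ± 0.80. The groups overlapped for dnajb1b and hsp70l, and the hsp70l value rests on control food 7, at 490.5 CPM against 63.42 and 37.48 CPM in the other controls and 39.98, 58.67 and 46.66 CPM with PFF food. Nuclear genes of oxidative phosphorylation were higher (adjusted p = 0.0336, and 0.916 with an estimated correlation), with 70 of 94 above 0. The subunit genes cox4i2, ndufa7 and cox7c stood at 1.45 ± 0.42, 0.83 ± 0.335 and 0.54 ± 0.28. No member of these 3 lists passed, over all genes or adjusted over the list alone. The microglial activation list was not called (adjusted p = 0.347, median 0.179, 21 of 37 above 0), nor was the homeostatic microglia list (adjusted p = 0.221, median 0.218, 14 of 21 above 0). The fry test called 0 lists, while camera called 8 without PFF 2 and 9 without PFF 6. The smaller microglia-like cluster held 48, 28 and 4 of the 140, 186 and 61 microglia-like cells of PFF 2, 6 and 8. In control food 1, 5 and 7 it held 87, 16 and 33 of 198, 40 and 104. This mix was not tested as a source of the list calls.

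In the 4 wpf neuron-like cells no gene passed over all genes tested. Proenkephalin (penka), the precursor of opioid peptides, stood at 25.5 ± 7.27 CPM with PFF food and 62.5 ± 17.8 CPM with control food, a log2 fold change of -1.285 ± 0.26 (SE, n = 3; edgeR, adjusted p = 1), and DESeq2 called it. The stress peptide gene uts1 (urotensin 1) stood at 14.2 ± 3.72 against 29.4 ± 1.31 CPM (-1.06 ± 0.21), and the lactate transporter slc16a3b at 12.99 ± 1.96 against 25.6 ± 2.63 CPM (-0.97 ± 0.18). The synuclein genes sncb and sncgb stood at -0.33 ± 0.19 and -0.50 ± 0.20, with each PFF library below each control-food library, and sncga at -0.29 ± 0.33.

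Of 17874 genes tested, 0 passed in edgeR, 502 had an unadjusted p under 0.05, and DESeq2 called 1 (penka). Further lower values that did not pass were those of the receptor gene fgfrl1a (-1.005 ± 0.21) and the glycolytic mutase pgam1a (-0.87 ± 0.19). Higher values that did not pass were those of the kinase rskra (0.77 ± 0.15) and the immune-type receptor dicp1.9 (1.102 ± 0.31). The reproductive peptide kiss2 (4.00 ± 1.17) did not pass either, and its 19.2 ± 28.4 CPM with PFF food and 1.197 ± 0.197 CPM with control food overlapped. For elavl3 the value was 0.07 ± 0.25. Without PFF 6, 1 gene passed, urp1, of the urotensin family, lower.

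**Figure D4:**
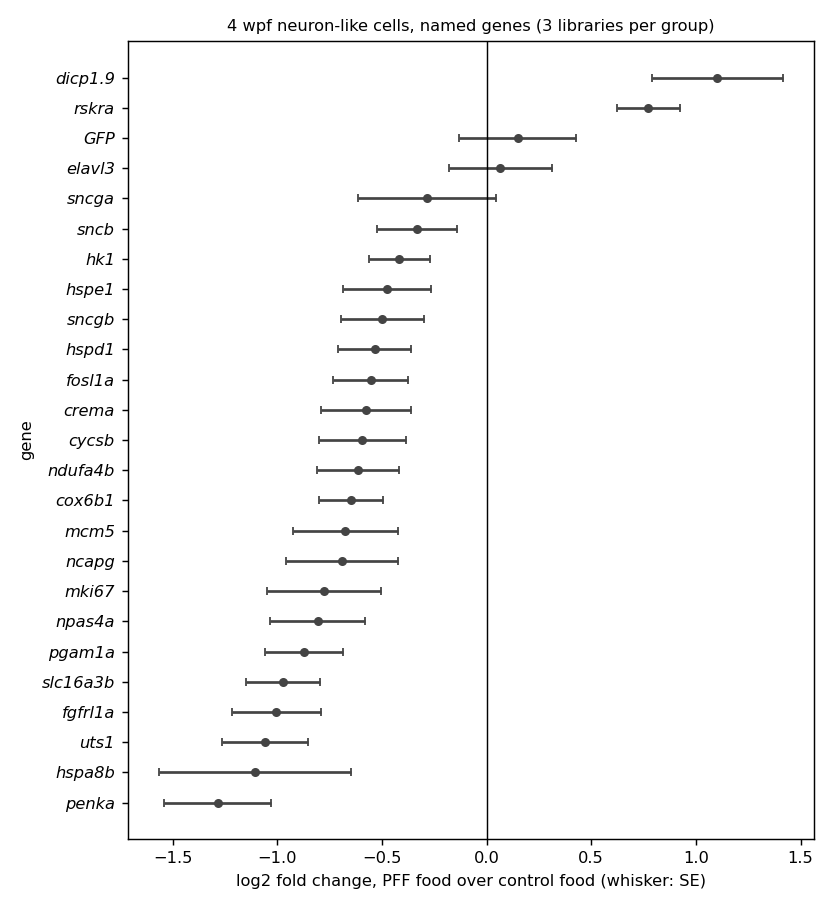
Log2 fold change, PFF over control food, of named genes in the 4 wpf neuron-like cells, with the SE of the edgeR estimate (3 libraries per group). Not every named gene is drawn: kiss2 and agrp, among those left out, lie outside the range shown. The values drawn run from 1.102 for dicp1.9 to -1.285 for penka, and none passed over all genes tested.

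Camera called 17 of 31 lists in the 4 wpf neuron-like cells, 15 lower and 2 higher, and none with an estimated correlation or with fry. Of the 10 ways to split the 6 libraries, 4 gave at least 17 calls. These sums pool several neuron clusters, and a different mix of them between libraries was not tested as a source. Neuropeptides were lower (adjusted p = 5.68e-17, and 0.331 with an estimated correlation), with 30 of 40 below 0 and a median of -0.701. Adjusted over the list alone 8 fell, 1 rose (kiss2) and 31 did not pass. Among those that fell were uts1, penka and agrp, the agouti-related feeding peptide, with 2 UMIs with PFF food and 94 with control food, a 28.3-fold lower rate (95% counting interval 7.63 to 237). Nuclear genes of oxidative phosphorylation were lower (adjusted p = 5.68e-17, and 0.583 with an estimated correlation), with 90 of 101 below 0 and a median of -0.284. Of these, cox6b1 stood at -0.65 ± 0.15, ndufa4b at -0.61 ± 0.195 and cytochrome c (cycsb) at -0.59 ± 0.21, and none passed over the list alone. Glycolysis genes were lower (adjusted p = 1.39e-10, and 0.449 with an estimated correlation), with 31 of 40 below 0; adjusted over the list alone 2 fell, slc16a3b and pgam1a, and 38 did not pass, hexokinase 1 (hk1, -0.42 ± 0.15) among them.

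Further lists called lower held genes of other cell functions, and none of their members passed, over all genes or adjusted over the list alone. Cell cycle genes (adjusted p = 4.61e-13, and 0.506 with an estimated correlation) had 59 of 67 members below 0, with mki67 at -0.78 ± 0.27, mcm5 at -0.675 ± 0.25 and ncapg at -0.69 ± 0.27. The immediate-early and dissociation list (adjusted p = 4.03e-08, and 0.506 with an estimated correlation) had 55 of 71 below 0, with npas4a at -0.81 ± 0.23, fosl1a at -0.55 ± 0.18 and crema at -0.58 ± 0.22. Cytosolic chaperones (adjusted p = 2.09e-07, and 0.331 with an estimated correlation) had 50 of 56 below 0, with the mitochondrial chaperonin genes hspd1 and hspe1 at -0.535 ± 0.175 and -0.475 ± 0.21 and hspa8b at -1.11 ± 0.46. Cholesterol and lipid synthesis (adjusted p = 1.82e-06, and 0.506 with an estimated correlation) had 36 of 45 below 0, and the synaptic vesicle cycle (adjusted p = 3.25e-06, and 0.506 with an estimated correlation) 37 of 45. The antioxidant response (adjusted p = 2.07e-05, and 0.331 with an estimated correlation) had 47 of 57 below 0, and the proteasome (adjusted p = 2.85e-05, and 0.78 with an estimated correlation) 46 of 52. Dopamine and monoamine handling (adjusted p = 0.00407, and 0.506 with an estimated correlation) had 24 of 31 below 0 and a median of -0.212.

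The remaining calls in the neuron-like cells were as follows. Radial glia and gliosis genes (adjusted p = 0.00327, and 0.78 with an estimated correlation), neurogenesis genes (0.00664, and 0.78 with an estimated correlation), myelin genes (0.028, and 0.78 with an estimated correlation) and the unfolded protein response (0.038, and 0.736 with an estimated correlation) were lower. Autophagy and mitophagy genes were higher (adjusted p = 0.00889, and 0.583 with an estimated correlation), with 40 of 59 above 0, as were complement genes (adjusted p = 0.0229, and 0.603 with an estimated correlation), with 10 of 13 above 0. Orthologs of Parkinson disease genes were not called (37 tested, adjusted p = 0.18, median -0.06, 22 below 0), nor was the lysosome list (adjusted p = 0.67, 42 of 73 above 0).

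In the 4 wpf radial glia-like cells no gene passed. The libraries of these sums also split in another way: setting control food 1, PFF 2 and PFF 6 against the rest called 1430 genes, where the real groups called 0. The Wnt antagonist sfrp5 stood at 42.3 ± 10.6 CPM with PFF food and 94.6 ± 2.43 CPM with control food (-1.15 ± 0.21, SE, n = 3; edgeR, adjusted p = 0.92). The retinoic acid-binding crabp1a stood at 246 ± 88.8 against 571 ± 24.4 CPM (-1.21 ± 0.28) and the homeobox gene otpa at -1.65 ± 0.345, with rgs5b at -1.34 ± 0.24 and the T-box gene tbx3a at -1.30 ± 0.30. The guidance receptor robo4 stood at 188 ± 16.9 against 110 ± 7.87 CPM (0.78 ± 0.17), the translation repressor eif4ebp3 at 1.06 ± 0.25, the kinase gene mknk2b at 0.73 ± 0.18, trib1 at 0.78 ± 0.20 and the cytokine inhibitor socs1a at 0.69 ± 0.18. The values of GFP, elavl3, sncb, sncga and sncgb were -0.67 ± 0.58, -0.785 ± 0.255, -0.69 ± 0.47, 0.63 ± 0.20 and -0.41 ± 0.50. Of 16830 genes tested, 0 passed in edgeR, 631 had an unadjusted p under 0.05, and DESeq2 called 7, all lower, among them otpa, otpb, sfrp5, rgs5b and crabp1a.

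Summed over all cells at 4 wpf, 0 of 21820 genes passed in edgeR, with 426 at an unadjusted p under 0.05 and 24 called by DESeq2. The collagens col1a1b, col1a1a, col1a2 and col2a1a stood at -1.26 ± 0.26, -2.19 ± 0.47, -1.215 ± 0.29 and -2.50 ± 0.66, and penka at -1.35 ± 0.32 (SE, n = 3; edgeR, adjusted p = 1). The col2a1a value rests largely on control food 1, at 142 CPM against 16.49 and 39.43 CPM in 5 and 7, and that of col1a1a on control food 5, at 148.2 CPM against 52.98 and 37.42 CPM in 1 and 7. These collagens were leading genes of a fibroblast or meninges cluster. The amount of that tissue in each library was not separated from a change within cells. The stress regulator nupr1b stood at 27.2 ± 0.913 CPM with PFF food and 16.2 ± 1.36 CPM with control food (0.75 ± 0.17), the mTORC1 inhibitor ddit4 at 0.505 ± 0.17, the phosphatidate phosphatase lpin1a at 1.44 ± 0.46, robo4 at 0.53 ± 0.18 and ndufb11 at 0.63 ± 0.23. For lpin1a the groups overlapped, with PFF 8 at 73.01 and control food 5 at 73.68 CPM, and the PFF mean rests largely on PFF 2, at 224.7 CPM. The values of GFP, elavl3, sncb, sncga and sncgb were 0.02 ± 0.37, 0.13 ± 0.22, -0.26 ± 0.23, 0.06 ± 0.31 and -0.49 ± 0.23. Without control food 1, 1 gene passed and without control food 7, 2 did, the parvalbumin genes pvalb4 and pvalb2, lower.

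The estimated log2 fold changes for aSyn at 5 dpf and for PFF food at 4 wpf in neuron-like cells were weakly correlated across genes. Spearman's correlation of the log2 fold changes over 16788 genes, which are not independent replicates, was 0.0947, with an SD of 0.0719 over the fits with a library left out and a range from -0.054 (without control A) to 0.19 (without control B). The 2 comparisons share no library. Over genes with a mean of at least 10 CPM it was 0.1705. Neither comparison called a gene in these cells, so no calls could be shared. Noise in the estimated fold changes lowers such a correlation, so the low value does not show that the effects are unrelated.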

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

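The tests of the patterns below were chosen only after seeing the results, except the neutrophil marker test and the splits of the libraries, which were fixed before.

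At 5 dpf, 17 genes had an aSyn effect that differed between the microglia-like and the neuron-like cells (edgeR with the library as a block, 16159 genes tested, 799 at an unadjusted p under 0.05); 12 were higher and 5 lower in the microglia-like cells. The chemokine gene ccl38a.3 led, with a difference of log2 fold changes of 5.29 ± 0.64 (SE; adjusted p = 1.29e-07). Other genes among them were csf3b (-5.24 ± 0.90, adjusted p = 0.000988), icn (2.73 ± 0.53, adjusted p = 0.00767), tox2 (2.13 ± 0.44, adjusted p = 0.0168), lsp1b (-3.06 ± 0.66, adjusted p = 0.0252) and ccl36.1 (adjusted p = 0.0329). The neuropeptide genes agrp, npy and gal, also among the 17, had too few counts in the microglia-like cells for a test of their own, as free RNA from neurons can give. Of 10 splits of the libraries, 5 gave at least 17 such genes, with 38 the highest among the others and also among those that part every letter pair.

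At 4 wpf, 3 genes had a PFF effect that differed between these classes (16326 tested, 539 at an unadjusted p under 0.05): mfap4.11 and agr2, lower in the microglia-like cells, and si:dkey-200l5.4, higher (3.66 ± 0.58), each with an adjusted p of 0.0295. The last was also a leading gene of the 4 wpf oligodendrocyte cluster, and oligodendrocyte markers in the microglia-like sums stood at 1265 ± 856 CPM with PFF food and 429 ± 263 CPM with control food (SD, n = 3), so free RNA from oligodendrocytes remains open for it. Only 1 of 10 splits, the real one, gave 3, and the highest other gave 2. The radial glia-like cells differed from the neuron-like cells in 0 genes at both ages, with 447 and 932 genes at an unadjusted p under 0.05. With 10 splits no share can fall under 0.05.

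The near absence of mfap4.7, mfap4.8 and mfap4.11 from the PFF microglia-like cells may reflect the fish rather than the food. Among the 6 libraries at 5 dpf, none fed PFF, 3 had at most 3 UMIs of these genes while others had up to 228. A gene copy or variant carried by only some fish would give this. Few cells of the expressing kind in a library would give it too. The 5 dpf libraries held only 19 to 51 microglia-like cells, in 1 cluster, so the 5 dpf counts cannot tell these apart. A different mix of the microglia-like clusters was argued against. The smaller cluster, which held nearly all of these UMIs, had 660 UMIs in 136 control-food cells and 0 in 80 PFF cells. With 0.5 UMI added, the log2 difference within it was -7.551 (half-width of the 95% interval 2.925), and its size depends on that addition. PFF 8 held only 4 cells of this cluster, and a different mix of cells within the cluster was not tested. Reads assigned to a near-identical copy remain open, since all mfap4 genes together differed by -196.4 CPM (half-width 499.5). An effect of PFF on these genes is not excluded, and genotyping the fish would separate it from a variant.

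The larger share of microglia-like cells with PFF food could come from the fish or from the preparation. Without the unnamed clusters of low UMI count the difference was 0.756 percentage points (half-width of the 95% interval 0.838), so barcodes of low depth in the control-food libraries remain open as part of it. Against the other glial and vascular cells the log2 ratio was 0.968 (half-width 1.113; 7.09 ± 1.59 and 3.76 ± 1.40 microglia-like cells per 100), so a different mix of dissociated cells is open too. Counts of microglia in fixed brain sections would test it.

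Neutrophils remain open as a source of the lower il1b, cxcl8a, csf3b and tnfb in the 5 dpf aSyn microglia-like cells. Neutrophil markers in the same sums differed by -0.944 in log2 (half-width of the 95% interval 0.945) and the 4 genes by -2.48 (half-width 1.532). The difference between these was 1.536 (half-width 1.133), so the 4 genes fell by more than the markers. The markers fell too, at 535.6, 1019 and 657.3 CPM in aSyn A, B and C and 1477, 1041 and 1665 CPM in controls A, B and C. The 4 genes were seen to be lower in these same data, so their larger fall does not exclude neutrophils. A weaker dissociation response is open: the median of the immediate-early and dissociation list was 0.252, the opposite sign to that explanation, but its adjusted p was 0.836 with an estimated correlation. Staining of il1b in undissociated larvae would test both.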

How the results depend on the processing

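With 3 libraries per group no exact test of a share can pass 0.05. In counts drawn with known folds, edgeR recovered 10.4% (all cells) to 53% (neuron-like) of the genes changed by a log2 fold of 1 at 5 dpf, so changes of that size can be missed. Of 620 values of named genes under the other settings, 589 kept direction and call, as did 1089 of 1127 with a library left out. Most of these genes had not passed in the main fit, and for them this asked only for the same sign and again no pass. The settings share most of their counts, so these numbers say little on how reliable such values are. Unless stated, the cause of a change was not tested.

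Genes called under other settings were as follows. With DESeq2 the counts were 22 (all cells), 18 (microglia-like) and 2 (radial glia-like) at 5 dpf, and 24 (all cells), 1 (neuron-like), 7 (microglia-like) and 7 (radial glia-like) at 4 wpf. At 5 dpf, 0 genes were called in all cells with a mean CPM of 10 or more, with predicted doublets kept and with the replicate block. The 5 dpf microglia-like count was 3 with RLE factors, 200 with no filter on low counts, 2 with predicted doublets kept, 4 with counts thinned to the smallest total, 3 over genes at least as high in the class as in all cells, and 5 with the replicate block. The replicate block gave 1 in the 5 dpf neuron-like cells, and no filter on low counts gave 1 in the radial glia-like cells. The 4 wpf microglia-like count was 137 with no filter, 2 with a mean CPM of 10 or more, 0 with expression centred per library, 2 with thinned counts and 0 in the largest microglia-like cluster alone, a setting chosen after seeing the data. In that cluster mfap4.7, mfap4.8 and mfap4.11 had at most 1 UMI in a library and were not tested, so this 0 says nothing on them. The age comparison gave 4990 with a mean CPM of 10 or more, where fewer genes are tested, and the correlation of neuron-like effects was 0.1705.

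Leaving out a library gave 0 to 5 genes in all cells at 5 dpf, 0 to 1 in microglia-like and 0 to 5 in radial glia-like cells. At 4 wpf it gave 0 to 2 genes in all cells, 0 to 1 in neuron-like and 0 to 13 in microglia-like cells. List calls by camera ranged from 4 to 8 (neuron-like) and 3 to 7 (microglia-like) at 5 dpf and from 4 to 9 in the 4 wpf microglia-like cells.

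Camera with an estimated correlation called 0 lists in each of these classes, as did fry (0). The 5 dpf neuron-like lists were 9 with a mean CPM of 10 or more and 10 with the replicate block. With the replicate block and an estimated correlation, chosen after seeing the data, they were 0, as were those of the 5 dpf microglia-like cells (0). The replicate block changed no call beyond those given here and in the report (sncga reversed to -0.173).

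Reversed values were few. The 4 wpf neuron-like share difference was -2.9796 with at least 1000 UMIs per cell, -14.1426 at Leiden resolution 0.5, where the low-UMI cluster took the neuron name, and -4.8876 without the unnamed clusters of low UMI count, chosen after seeing the data. GFP in all cells at 4 wpf was -0.005 with DESeq2 and -0.006 with RLE factors. With a library left out, the log2 fold change at 5 dpf ranged from -1.14 to 0.519 (sncga) and -0.157 to 0.041 (sncgb) in neuron-like cells. In radial glia-like cells it ranged from -0.371 to 0.136 (sncb), -0.168 to 0.482 (sncga) and -0.229 to 0.137 (sncgb). At 4 wpf it ranged from -0.297 to 0.39 (GFP) and -0.191 to 0.424 (sncga) in all cells and from -0.203 to 0.341 (GFP) in neuron-like cells. The microglia-like range was -0.12 to 0.618 (elavl3) and -1.688 to 1.071 (sncgb), and the radial glia-like range -0.791 to 0.037 (sncgb).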

Other observations

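The 4 wpf control-food fish and the 5 dpf aSyn larvae, which both carry the transgene, differed in 9914 genes over all cells (edgeR, n = 3), but age, diet, the Cell Ranger version and the preparation changed together and cannot be told apart. Cell cycle genes were higher at 4 wpf: 66 of 69 rose and 1 fell, and adjusted over the list alone 67 rose and 1 fell (camera, adjusted p = 1.72e-40, and 0.817 with an estimated correlation). Among the largest rises were tyms (4.81 ± 0.50, SE) and pclaf (4.78 ± 0.40) of DNA replication, and hmgcra (5.19 ± 0.30), elovl2 (5.31 ± 0.32) and fads2 (4.62 ± 0.22) of sterol and fatty acid synthesis. Neurogenesis genes were higher, with 57 of 69 rising and 2 falling (adjusted p = 9.73e-18, and 0.817 with an estimated correlation), as were cholesterol and lipid synthesis genes, with 28 of 46 rising and 7 falling (adjusted p = 2.98e-10, and 0.817 with an estimated correlation). The mix of cells also differed between the ages, and these sums do not separate it from changes within a cell type. The neuronal gene elavl3 rose by 1.21 ± 0.28 (adjusted p = 0.00836) over all cells, but within neuron-like cells it stood at 2499.0, 2582.4 and 2558.6 CPM at 5 dpf and at 2596.5, 2845.8 and 2516.2 CPM at 4 wpf, without scaling by TMM factors.

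Ribosomal protein genes were lower at 4 wpf, with 64 of 91 falling and 0 rising (adjusted p = 4.83e-08, and 0.848 with an estimated correlation), as were glucocorticoid response genes, with 15 of 22 falling (adjusted p = 3.19e-06, and 0.817 with an estimated correlation). Among the largest falls were the ion transport genes atp1a1a.2 (-10.76 ± 0.74) and rhcga (-9.51 ± 0.66), the keratin krt92 (-10.66 ± 0.89) and lgals2b (-10.45 ± 0.66), which are genes of skin and gut. Only 1 of 10 splits, the real one, gave as many genes, and the highest other gave 0.

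The following split tests were fixed before the results were seen. Each comparison has 10 splits of its 6 libraries into 3 and 3, so that no share can fall under 0.05. For genes at 5 dpf, the count in all cells (1) was reached in 1 of 10 splits, with 0 the highest other. The counts of 0 were reached in 10 of 10, with 0 the highest other in neuron-like, 2 in microglia-like and 1 in radial glia-like cells. Among the 3 other splits that part every letter pair the highest were 0 (all cells), 0 (neuron-like), 1 (microglia-like) and 0 (radial glia-like). At 4 wpf the 4 genes of the microglia-like cells were reached in 1 of 10 splits, with 0 the highest other, and the counts of 0 in all cells, neuron-like and radial glia-like cells in 10 of 10, with 2, 1 and 1430 the highest others. The split with 1430 genes put control food 1 with PFF 2 and PFF 6, which points to a structure of the samples that the labels do not name. These 3 libraries also had the highest median mitochondrial percentages at 4 wpf, 3.8593, 4.0562 and 3.0881, against 2.6877 and 2.3937 in control food 5 and 7 and 2.6141 in PFF 8. RNA or cell quality therefore remains open as its source.

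For gene lists at 5 dpf, the 4 calls in neuron-like cells were reached in 9 of 10 splits, with 16 the highest other and 9 the highest that parts every letter pair, and the 6 in microglia-like cells in 3 of 10, with 8 and 4. At 4 wpf the 17 calls in neuron-like cells were reached in 4 of 10, with 18 the highest other, and the 5 in microglia-like cells in 10 of 10, with 13.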
